A study of Arabidopsis thaliana with 15 samples.

How the data were processed

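The samples were leaves of Arabidopsis thaliana Col-0 in 5 groups of 3 arrays. They were day 0, day 4 with normal or salt watering, and day 7 after Botrytis cinerea inoculation following either watering. Per the labels' protocols, each infected replicate pooled inoculated leaves (2 leaves from each of 3 plants), RNA came from 200 mg of leaf, Cy3-labelled cDNA was hybridised to 1-colour NimbleGen arrays, and replicates came from separate leaves. Replicates are therefore taken as biological, and p-values measure the spread between these leaf samples.

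The authors deposited a table with 1 intensity per feature and array on a linear scale. Per the submitters' processing notes it was made with RMA, which by definition corrects background, quantile-normalises between arrays and summarises probes. The version, settings, probe annotation and genome build are not given in the sources used here. Normalisation between arrays assumes similar overall distributions, so a shift of most transcripts in 1 direction would be partly removed. Near the ends of the range, background and saturation narrow differences. The 25th and 75th percentiles of mean intensity per locus were 63.4 and 2360.2.

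From the 37118 features, log2 intensities were taken, and for each of 32627 loci the feature with the highest mean over all arrays was kept (29025 loci had 1 feature and 3602 several). Loci were named through the RefSeq gene table of assembly TAIR10.1, which held 31993 of them. A symbol was found for 10603 and none for 22024. No chromosome positions are given, as the authors' build is unknown.

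All 15 arrays entered 1 linear model per gene with a mean per group, fitted with limma 3.58.1 (lmFit and eBayes, default settings, R 4.3.3, statmod 1.5.0), with 10 residual degrees of freedom, 2.50 prior degrees of freedom and a prior SD of 0.156. There were 7 contrasts, each adjusted by the Benjamini-Hochberg method over 32627 genes, with a threshold of 0.05 on the adjusted p, 2-sided. Counts with at least a 2-fold change are given beside these.

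For 28 gene lists with 426 members (421 loci, 420 on the array, NIMIN2 being absent), limma's camera with a preset correlation of 0.01 tested each list against the other genes, 2-sided, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it, and members were also counted adjusted over the list alone. The lists cover ABA and dehydration responses, ABA metabolism and signalling, ion transport and osmolytes, camalexin, jasmonate (3 lists), salicylate, pattern-triggered immunity, ethylene, photosynthesis (2 lists), senescence, phenylpropanoids, flavonoids, glucosinolates (2 lists), the cuticle, heat shock, oxidative stress, hypoxia, the clock (2 lists), guard cells, the phloem, trichomes, dividing cells and reference genes.

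Genes were named by a fixed rule. It took, per comparison, the 10 largest rises and 10 largest falls among genes with a symbol that passed and whose groups did not overlap (5 in place of 10 for the day 0 to day 4 and the joint comparison, and no overlap criterion for the interaction). It added up to 4 members of each list with the smallest adjusted p, or the 2 with the largest change where none passed, and 13 fixed marker genes in every comparison. The groups, contrasts, tests, lists, naming rule and the settings listed next were chosen before the data were examined.

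Other settings were quantile normalisation, median centring, leaving out a share of 0.25 of the features, the dimmest, testing every feature, eBayes with trend and robust, array weights, fitting only the groups compared, the replicate number as a block, each array left out in turn, and a 2-fold or 1.5-fold (treat) minimum. Chosen after the data were seen were day 0 leaves as the control, scaling to the 8 reference genes, the leading residual component as a covariate, gene-by-gene array weights and a set of gene families. Agreement between contrasts was measured by correlation across genes, and chance agreement through shared arrays by 100 simulations of unchanged groups (seed 1).

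The model was tested on simulated data for 32627 genes. For salt against water, 53.7%, 65.7% and 100% of genes changed 1.5-fold, 2-fold and 4-fold were recovered (67, 67 and 66 genes), with 19 false calls. For infection the shares were 47.8%, 67.2% and 98.5% with 10 false calls. For salt in infected leaves they were 55.2%, 65.7% and 100% with 6, and for the interaction 22.4%, 44.8% and 83.3% with 6.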

Results

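Gene expression was measured on 1-colour NimbleGen arrays, 15 in all, in rosette leaves of Arabidopsis thaliana Col-0, the standard laboratory accession. The 5-week-old plants grew at 22 °C with 8 h of light per day. There were 5 groups of 3 arrays. Day 0 leaves came from plants before any treatment. Watered leaves and salt-watered leaves were taken on day 4, after normal watering or watering with 150 mM NaCl (25 ml per pot). Infected leaves and salt-watered infected leaves were taken on day 7, 3 days after 5 µl drops of spores of Botrytis cinerea had been set on plants from either watering. Botrytis cinerea, the grey mould fungus, kills plant tissue and feeds on it. The design asks what salt alone does, what the fungus does with and without prior salt, and whether the responses combine. No uninfected day 7 leaves are among the samples used here, so the later day, the spore broth and the clear cover kept over inoculated plants all go with infection, and whether salt watering went on after day 4 is not stated. The median intensity of an array lay between 361 and 427, and single values ranged from 11.1 to 45666. Arrays of a group correlated at r = 0.980 to 0.997. The leading principal component held 78.0% of the variance and separated infected from uninfected arrays. On it, infected replicate 2 lay at 123, apart from the other infected arrays without salt (60.8 and 74.4) and towards the salt-watered infected arrays (169 to 172). The number of arrays, 3 per group, limits the precision of every value. Below, a gene rose, fell or changed where limma gave an adjusted p under 0.05. The ± after a log2 change is its standard error from the fit (n = 3 per group), and the ± after a log2 intensity is the SD of 3 arrays.

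**Figure D1:**
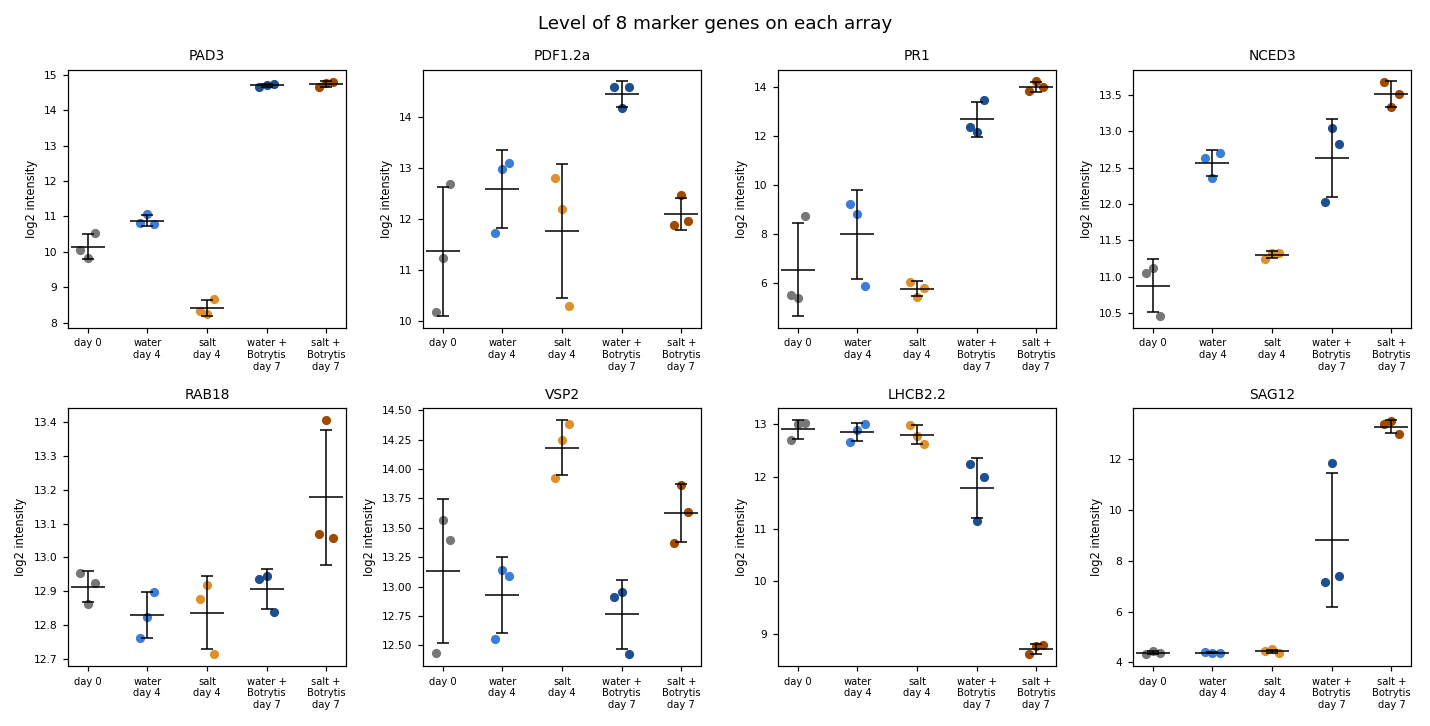
Log2 intensity of 8 markers in 5 groups, with a point per array and mean ± SD bars (n = 3). RAB18 here is AT1G43890, not the AT5G66400 of the text. PAD3 was 10.88 ± 0.16 in watered, 8.41 ± 0.23 in salt-watered, 14.71 ± 0.04 in infected and 14.74 ± 0.08 in salt-watered infected leaves. SAG12 was 8.80 ± 2.64 and 13.26 ± 0.27 in the infected groups.

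After 4 days, salt-watered leaves had more transcript of anthocyanin genes and less of camalexin and pattern-triggered immunity genes than watered leaves. GSTF12 (AT5G17220), a glutathione transferase needed to carry anthocyanin pigments into the vacuole, was 44.4-fold higher (log2 change 5.47 ± 0.43, n = 3 per group). The anthocyanin enzymes DFR (AT5G42800) and LDOX (AT4G22880) were 29.2-fold and 24.9-fold higher (4.87 ± 0.37 and 4.64 ± 0.39), and the glycosyltransferase UF3GT (AT5G54060) 18.1-fold higher (4.18 ± 0.34). PAD3 (AT3G26830), which makes the last step to the antifungal compound camalexin, was 5.52-fold lower (-2.47 ± 0.16). WRKY22 (AT4G01250), a transcription factor of pattern-triggered immunity, was 8.59-fold lower (-3.10 ± 0.18), and CYP81F2 (AT5G57220), which modifies indole glucosinolates, 12.5-fold lower (-3.65 ± 0.14). In all, 4347 of 32627 genes changed, of which 1994 rose and 2353 fell, and 1251 of these passed 2-fold (297 up, 954 down). Among the other largest rises were MYB114 (AT1G66380) (3.13 ± 0.46) and MYB75 (AT1G56650) (3.03 ± 0.29), which switch on anthocyanin genes, the Nudix hydrolase NUDT24 (AT5G19470) (2.62 ± 0.25), the beta-glucosidase BGLU11 (AT1G02850) (2.61 ± 0.31) and DR4 (AT1G73330) (3.04 ± 0.66). The lipid transfer protein gene LTP3 (AT5G59320) also rose (4.40 ± 1.13), but not without watered replicate 1 or 2 or salt-watered replicate 1 or 2 (adjusted p = 0.0682 to 0.0769). The largest falls were those of PHI-1 (AT1G35140) (-5.76 ± 0.48), PP2-A5 (AT1G65390) (-5.13 ± 0.54), PP2-B13 (AT1G56240) (-5.05 ± 0.29) and TCH4 (AT5G57560) (-4.49 ± 0.30), a touch-induced xyloglucan endotransglucosylase of the cell wall. AACT1 (AT5G61160) (-4.10 ± 0.47), the ethylene response factor RRTF1 (AT4G34410) (-4.04 ± 0.53), the calmodulin-like CML38 (AT1G76650) (-4.00 ± 0.33), DIN11 (AT3G49620) (-3.65 ± 0.26) and the gibberellin-inactivating oxidases GA2OX6 (AT1G02400) (-4.01 ± 0.39) and GA2OX2 (AT1G30040) (-3.73 ± 0.28) followed.

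Of 28 gene lists, camera called 12 in this comparison, 2 higher and 10 lower. With an estimated correlation between genes it called 0 (8 at unadjusted p under 0.05), and fry called 16. Medians below are of the log2 changes of a list. In flavonoid and anthocyanin synthesis, 8 rose and 1 fell of 15 (9 and 1 adjusted over the list alone). The median was 1.01 (adjusted p = 1.76e-06, and adjusted p = 0.153 with an estimated correlation). In aliphatic glucosinolate synthesis, which makes methionine-derived defence compounds, 6 of 16 rose (13 adjusted over the list alone), with MYB76 (AT5G07700) at 1.22 ± 0.17 and BCAT4 (AT3G19710) at 0.71 ± 0.11. The median was 0.51 (adjusted p = 4.33e-07, and adjusted p = 0.235 with an estimated correlation). In pattern-triggered immunity, the response to microbial molecules, 15 of 25 fell (16 adjusted over the list alone). The median was -0.63 (adjusted p = 4.34e-14, and adjusted p = 0.0687 with an estimated correlation). Its members PEPR1 (AT1G73080), a receptor of danger peptides, and the kinases MKK4 (AT1G51660) and BIK1 (AT2G39660) stood at -1.82, -0.93 and -0.96. In camalexin and tryptophan synthesis, 11 of 18 fell (12 adjusted over the list alone). The median was -0.52 (adjusted p = 1.34e-10, and adjusted p = 0.0651 with an estimated correlation). GSTF6 (AT1G02930) (-2.02 ± 0.14), WRKY33 (AT2G38470) (-1.40 ± 0.12), the factor that switches on PAD3, and ASB1 (AT1G25220) (-1.02 ± 0.11) fell beside PAD3. In salicylate synthesis and response, 13 of 20 fell (15 adjusted over the list alone), among them CBP60G (AT5G26920) (-2.20 ± 0.21) and SARD1 (AT1G73805) (-1.71 ± 0.25), factors that switch on salicylate synthesis, and the transporter EDS5 (AT4G39030) (-1.26 ± 0.13). The median was -0.86 (adjusted p = 1.34e-10, and adjusted p = 0.142 with an estimated correlation). For the jasmonate/ethylene defence branch, 9 of 16 fell (9 adjusted over the list alone), with the ethylene response factors ERF6 (AT4G17490), ERF5 (AT5G47230) and ERF104 (AT5G61600) at -2.00, -1.85 and -1.82. The median was -1.17 (adjusted p = 2.24e-06, and adjusted p = 0.153 with an estimated correlation). In the jasmonate MYC branch, 2 rose and 10 fell of 14 (2 and 11 adjusted over the list alone), with NAC055 (AT3G15500) (-2.94 ± 0.18), JAZ7 (AT2G34600) (-2.73 ± 0.33) and the repressor JAZ1 (AT1G19180) (-1.28 ± 0.12) lower. The median was -0.92 (adjusted p = 7.69e-07, and adjusted p = 0.235 with an estimated correlation).

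In jasmonate synthesis and breakdown, 7 of 16 fell (8 adjusted over the list alone), including AOC3 (AT3G25780) (-2.87 ± 0.38) and LOX4 (AT1G72520) (-2.23 ± 0.30), enzymes early in jasmonate synthesis. The median was -0.33 (adjusted p = 0.000345, and adjusted p = 0.358 with an estimated correlation). In ethylene synthesis and signalling 5 of 11 fell (5 adjusted over the list alone), led by ACS6 (AT4G11280) (-1.58 ± 0.15) and ACS8 (AT4G37770) (-3.24 ± 0.48), which make the ethylene precursor. The median was -0.17 (adjusted p = 0.000549, and adjusted p = 0.0651 with an estimated correlation). In leaf senescence 6 of 18 fell (6 adjusted over the list alone), led by SAG21 (AT4G02380) (-2.68 ± 0.12) and WRKY53 (AT4G23810) (-2.96 ± 0.22). The median was -0.16 (adjusted p = 0.000545, and adjusted p = 0.282 with an estimated correlation). For indole glucosinolates, 8 of 13 fell (8 adjusted over the list alone), with their regulator MYB51 (AT1G18570) at -1.59 ± 0.17. The median was -0.38 (adjusted p = 7.69e-07, and adjusted p = 0.0651 with an estimated correlation). The list of oxidative stress and detoxification was called lower, with a median above 0. In it 5 of 14 fell (1 rose and 5 fell adjusted over the list alone), with CSD1 (AT1G08830) (-0.88 ± 0.09) and ZAT10 (AT1G27730) (-1.80 ± 0.19) lower. The median was 0.02 (adjusted p = 0.0221, and adjusted p = 0.153 with an estimated correlation). The call of this list was lost without salt-watered replicate 3 (adjusted p = 0.0535). The other 16 lists were not called. In the ABA- and dehydration-responsive list, 6 rose and 4 fell of 25 (9 and 5 adjusted over the list alone, median 0.30, adjusted p = 0.401), with HB-7 (AT2G46680) higher (1.59 ± 0.26) and HAI1 (AT5G59220) lower (-1.89 ± 0.24). For ABA synthesis, breakdown and core signalling, 3 rose and 8 fell of 32 (5 and 9 adjusted over the list alone, median 0.04, adjusted p = 0.32). CYP707A3 (AT5G45340) fell (-3.12 ± 0.19) while CYP707A2 (AT2G29090), of the same family of ABA-degrading enzymes, rose (2.51 ± 0.27). The test of this list pointed down and its median up. For ion transport and osmolytes, 7 rose and 3 fell of 19 (7 and 3 adjusted over the list alone, median 0.10, adjusted p = 0.404). In the light reactions of photosynthesis 1 of 36 fell (1 adjusted over the list alone, median 0.00, adjusted p = 0.814), the member that fell being LHCB1.1 (AT1G29920) (-1.58 ± 0.20), and in the Calvin cycle 0 of 19 changed (0 adjusted over the list alone, median 0.02, adjusted p = 0.929). The counts were 1 rose and 1 fell of 15 (3 and 2 adjusted over the list alone) for phenylpropanoid and lignin synthesis, 1 rose and 2 fell of 17 (2 and 2 adjusted over the list alone) for cuticle synthesis and 2 rose and 2 fell of 10 (2 and 3 adjusted over the list alone) for hypoxia. They were 2 of 11 rose (2 adjusted over the list alone) for heat shock proteins and 1 rose and 1 fell of 7 (1 and 1 adjusted over the list alone) for evening-phased clock genes (adjusted p = 0.264 to 0.959). Among morning-phased clock genes 1 of 7 fell (1 adjusted over the list alone, median 0.06, adjusted p = 0.964), the test pointing down. Of the cell type markers, 1 rose and 2 fell of 9 (1 and 3 adjusted over the list alone) for guard cells, 1 of 4 rose (1 adjusted over the list alone) for the phloem, 0 of 4 changed (0 adjusted over the list alone) for trichomes and 1 of 6 fell (1 adjusted over the list alone) for dividing cells (adjusted p = 0.0689 to 0.467). Of the reference genes 0 of 8 changed (0 adjusted over the list alone, median 0.01, adjusted p = 0.977). At unadjusted p under 0.05, limma gave 0 Calvin cycle members, 0 reference genes and 1 trichome marker.

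Of the fixed markers not named so far, NCED3 (AT3G14440), the main ABA-producing enzyme of stressed leaves, fell (-1.26 ± 0.23), CYP71A13 (AT2G30770) of camalexin synthesis fell (-1.59 ± 0.28) and the jasmonate-induced VSP2 (AT5G24770) rose (1.25 ± 0.28). JAZ10 (AT5G13220) fell (-1.83 ± 0.56, adjusted p = 0.0475), but not without watered replicate 2 or 3 or salt-watered replicate 1 or 2 (adjusted p = 0.0921 to 0.2). The others were not called: RD29B (AT5G52300) 1.99 ± 0.65, RAB18 (AT5G66400) 0.69 ± 0.24, PDF1.2a (AT5G44420) -0.83 ± 0.66, PR1 (AT2G14610) -2.22 ± 0.90, LOX2 (AT3G45140) 0.07 ± 0.08, RBCS1A (AT1G67090) 0.01 ± 0.08, LHCB2.2 (AT2G05070) -0.06 ± 0.22 and SAG12 (AT5G45890) 0.07 ± 0.87. Without salt-watered replicate 1 or 2, 2728 or 2887 genes changed. With day 0 leaves as control, added after the data were seen, 562 genes changed (101 up, 461 down). Here GSTF12 was 1.82 ± 0.43 (adjusted p = 0.0539), DFR 2.97 ± 0.37, PAD3 -1.73 ± 0.16, WRKY22 -0.88 ± 0.18, PHI-1 -0.73 ± 0.48, RRTF1 0.17 ± 0.53, NCED3 0.43 ± 0.23, ACS6 0.00 ± 0.15 and HAI1 1.00 ± 0.24 (adjusted p = 0.0619). The jasmonate/ethylene, jasmonate synthesis, MYC and oxidative stress lists were not called. Dehydration-responsive and phloem genes were called up, guard and dividing cells down (adjusted p = 3.58e-05 to 0.00761), but not with an estimated correlation.

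**Figure D2:**
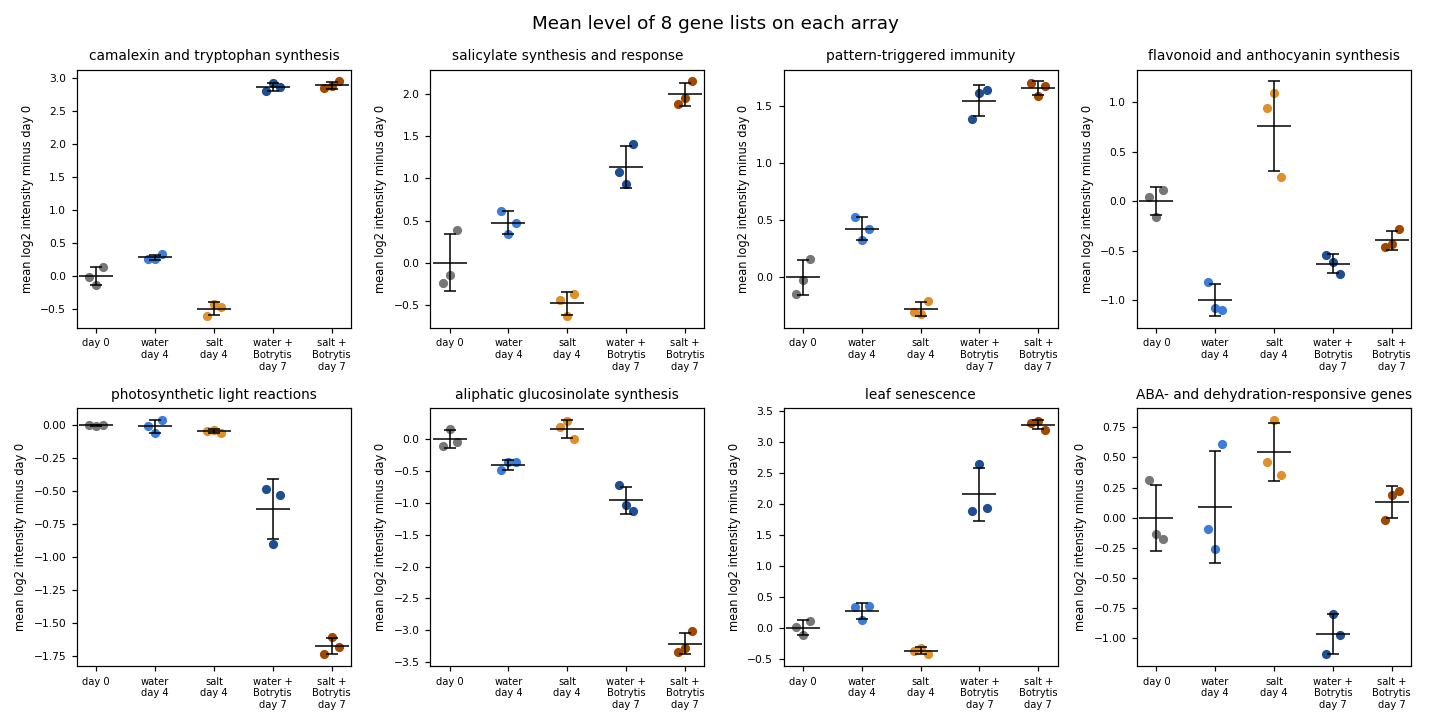
Mean log2 intensity of the members of 8 gene lists on each array, minus the day 0 mean, with a point per array and bars for the mean ± SD (n = 3). The light reactions stood at -0.64 ± 0.23 in infected and -1.68 ± 0.06 in salt-watered infected leaves, camalexin synthesis at 2.86 ± 0.06 and 2.89 ± 0.05, and leaf senescence at 2.16 ± 0.42 and 3.29 ± 0.08.

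Between day 0 and day 4, watered leaves themselves moved, and largely opposite to the salt contrast. PHI-1 rose by 5.03 ± 0.48 on the log2 scale (32.7-fold, n = 3 per group), TCH4 by 3.39 ± 0.30, RAS1 (AT1G09950) by 3.35 ± 0.31 and PP2-B13 by 3.30 ± 0.29, and RRTF1 was 18.4-fold higher. GSTF12 was 12.6-fold lower (-3.65 ± 0.43), followed by MYB114 (-2.46 ± 0.46), MYB75 (-2.38 ± 0.29), LDOX (-2.11 ± 0.39) and UF3GT (-2.08 ± 0.34). Of all genes 1394 changed (967 up, 427 down), and 515 passed 2-fold (430 up, 85 down). Without day 0 replicate 1 or 2 or watered replicate 3, the count was 746, 867 or 830. Camera called 10 lists, 8 higher and 2 lower, and 0 with an estimated correlation (5 at unadjusted p under 0.05), and fry called 10. For pattern-triggered immunity, 10 of 25 rose (13 adjusted over the list alone). The median was 0.40 (adjusted p = 7.61e-11, and adjusted p = 0.214 with an estimated correlation). WRKY22 (2.22 ± 0.18), PEPR1 (1.34 ± 0.16) and BIK1 (0.77 ± 0.10) rose. In the jasmonate MYC branch 7 of 14 rose (9 adjusted over the list alone), including NAC055 (2.06 ± 0.18) and JAZ1 (1.06 ± 0.12), and in the jasmonate/ethylene branch 4 of 16 rose (5 adjusted over the list alone), including ERF6 (1.62 ± 0.14) and ERF104 (1.63 ± 0.22). Their medians were 0.75 and 1.03 (adjusted p = 9.84e-09 and 4.21e-08, and adjusted p = 0.236 and 0.214 with an estimated correlation). For camalexin and tryptophan synthesis, 5 of 18 rose (6 adjusted over the list alone), with WRKY33 at 1.08 ± 0.12. The median was 0.20 (adjusted p = 3.62e-05, and adjusted p = 0.236 with an estimated correlation). PAD3 rose by 0.74 ± 0.16, but not without day 0 replicate 1 or 2 or watered replicate 2 (adjusted p = 0.0804 to 0.0935). For salicylate synthesis and response, 1 of 20 rose (6 adjusted over the list alone), the member being CBP60G (1.74 ± 0.21), and for jasmonate synthesis 4 of 16 rose (6 adjusted over the list alone). Their medians were 0.44 and 0.27 (adjusted p = 3.62e-05 and 0.00136, and adjusted p = 0.391 and 0.468 with an estimated correlation). The calls of the salicylate and jasmonate synthesis lists were lost with fry (adjusted p = 0.0644 and 0.0788). For indole glucosinolates 2 of 13 rose (4 adjusted over the list alone), and for leaf senescence 5 of 18 rose (7 rose and 1 fell adjusted over the list alone), with SAG21 at 1.48 ± 0.12 and WRKY53 at 1.59 ± 0.22. Their medians were 0.21 and 0.25 (adjusted p = 0.000127 and 0.00264, and adjusted p = 0.214 and 0.425 with an estimated correlation). For flavonoids 5 of 15 fell (7 adjusted over the list alone), and for aliphatic glucosinolates 2 of 16 fell (7 adjusted over the list alone). Their medians were -0.48 and -0.38 (adjusted p = 4.2e-07 and 3.63e-07, and adjusted p = 0.236 and 0.315 with an estimated correlation). The other 18 lists were not called, and for oxidative stress the test pointed up and the median (-0.02) down. Of the fixed markers NCED3 rose (1.69 ± 0.23). RD29B -0.49 ± 0.65, RAB18 0.02 ± 0.24, CYP71A13 0.39 ± 0.28, PDF1.2a 1.23 ± 0.66, PR1 1.44 ± 0.90, LOX2 -0.06 ± 0.08, VSP2 -0.21 ± 0.28, JAZ10 1.23 ± 0.56, RBCS1A -0.02 ± 0.08, LHCB2.2 -0.05 ± 0.22 and SAG12 0.00 ± 0.87 were not called. Of the 967 genes that rose with time, 899 (93.0%) fell with salt against the same watered leaves, where independent lists would share 69.7, and 354 genes rose with salt and fell with time. Across genes, which are not independent replicates, the log2 changes correlated at r = -0.790 and had a covariance of -0.129. Unchanged groups sharing the watered arrays, simulated 100 times, gave r = -0.501 and a covariance of -0.0222, so part of this overlap may come from the shared arrays.

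Infection of normally watered plants went with higher transcript of camalexin, lignin and heat shock genes and lower transcript of photosynthesis and cuticle genes. The Kunitz-type protease inhibitor gene KTI1 (AT1G73260) was 509.6-fold higher than in watered leaves on day 4 (8.99 ± 0.22, n = 3 per group), the alternative oxidase AOX1D (AT1G32350) 486-fold (8.93 ± 0.16), the fatty acid dioxygenase DOX1 (AT3G01420) 354-fold (8.47 ± 0.17) and the sterol desaturase CYP710A1 (AT2G34500) 329.9-fold (8.37 ± 0.13). PAD3 was 14.2-fold higher (3.83 ± 0.16) and the chitinase PR3 (AT3G12500) rose by 4.32 ± 0.30. GER3 (AT5G20630), a germin-like protein, was 68.9-fold lower (-6.11 ± 0.27) and CER1 (AT1G02205), which makes wax alkanes, 60.9-fold lower (-5.93 ± 0.27). In total 14616 genes changed (6440 up, 8176 down), and 6132 passed 2-fold (2577 up, 3555 down). Other large rises were those of the beta-glucosidase BGLU27 (AT3G60120) (8.35 ± 0.16), the cellulose synthase-like CSLG2 (AT4G24000) (8.03 ± 0.27), the osmotin-like OSM34 (AT4G11650) (7.91 ± 0.41), the transcription factor WRKY75 (AT5G13080) (7.76 ± 0.15), DXPS1 (AT3G21500) (7.73 ± 0.21) and the peroxidase Prx37 (AT4G08770) (7.47 ± 0.22). Other large falls were those of FKF1 (AT1G68050) (-5.17 ± 0.18), a blue light receptor of the clock, the cold regulator CBF1 (AT4G25490) (-5.11 ± 0.24), the cold-induced COR15B (AT2G42530) (-5.04 ± 0.15), the Rubisco assembly protein RbcX1 (AT4G04330) (-4.98 ± 0.60), the expansins EXPA16 (AT3G55500) (-4.96 ± 0.48) and EXPB1 (AT2G20750) (-4.73 ± 0.35), the gibberellin synthesis gene GA2 (AT1G79460) (-4.90 ± 0.25) and the galactinol synthase GOLS3 (AT1G09350) (-4.70 ± 0.20).

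Camera called 18 lists, 10 higher and 8 lower, and 0 with an estimated correlation (8 at unadjusted p under 0.05), and fry called 24. In camalexin and tryptophan synthesis 18 of 18 rose (18 adjusted over the list alone). The median was 1.97 (adjusted p = 2.35e-13, and adjusted p = 0.0658 with an estimated correlation). The transporter ABCG40 (AT1G15520) (6.28 ± 0.16), GSTU4 (AT2G29460) (6.73 ± 0.19) and the regulator NAC042 (AT2G43000) (3.75 ± 0.14) rose beside PAD3. For phenylpropanoid and lignin synthesis, 14 of 15 rose (14 adjusted over the list alone), with CCR2 (AT1G80820) of lignin synthesis at 4.96 ± 0.15. The median was 1.26 (adjusted p = 5.71e-09, and adjusted p = 0.0864 with an estimated correlation). For heat shock proteins 9 of 11 rose (9 adjusted over the list alone), with HSFA2 (AT2G26150), a heat stress transcription factor, at 6.20 ± 0.23. The median was 4.06 (adjusted p = 9.63e-08, and adjusted p = 0.0864 with an estimated correlation). For leaf senescence 13 rose and 1 fell of 18 (14 and 1 adjusted over the list alone), with WRKY75 and SAG13 (AT2G29350) (3.25 ± 0.13) up. The median was 1.42 (adjusted p = 9.05e-06, and adjusted p = 0.161 with an estimated correlation). The list mean relative to day 0 was 2.64 on infected replicate 2, against 1.89 and 1.93 on the other infected arrays. For indole glucosinolates 11 of 13 rose (11 adjusted over the list alone). The median was 0.84 (adjusted p = 8.36e-05, and adjusted p = 0.0932 with an estimated correlation). In pattern-triggered immunity 14 rose and 3 fell of 25 (14 and 3 adjusted over the list alone). The median was 0.40 (adjusted p = 0.000291, and adjusted p = 0.319 with an estimated correlation). NHL10 (AT2G35980) (6.55 ± 0.10) and the danger peptide precursor PROPEP3 (AT5G64905) (5.72 ± 0.21) rose. For the jasmonate MYC branch 9 of 14 rose (10 adjusted over the list alone), and for jasmonate synthesis 8 rose and 2 fell of 16 (10 and 2 adjusted over the list alone). Their medians were 0.49 and 0.38 (adjusted p = 0.00371 and 0.0398, and adjusted p = 0.446 and 0.52 with an estimated correlation). The call of jasmonate synthesis was lost without watered replicate 1 or 2 and with arrays centred on their medians (adjusted p = 0.0631 to 0.0762). For oxidative stress 9 rose and 3 fell of 14 (9 and 3 adjusted over the list alone). The median was 0.65 (adjusted p = 0.00199, and adjusted p = 0.0864 with an estimated correlation).

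Photosynthesis genes fell. In the light reactions 33 of 36 fell (35 adjusted over the list alone), including the antenna gene LHCB1.1 (-2.99 ± 0.20), and in the Calvin cycle 17 of 19 fell (17 adjusted over the list alone), including SBPASE (AT3G55800) (-0.93 ± 0.11). Their medians were -0.52 and -0.36 (adjusted p = 5.04e-09 and 0.000213, and adjusted p = 0.319 and 0.346 with an estimated correlation). For cuticle synthesis 10 of 17 fell (10 adjusted over the list alone), with CER4 (AT4G33790) at -3.70 ± 0.34. The median was -1.06 (adjusted p = 0.000213, and adjusted p = 0.161 with an estimated correlation). Relative to day 0, infected replicate 2 had list means of -0.90 for the light reactions (-0.48 and -0.53 on the other infected arrays), -0.73 for the Calvin cycle (-0.38 and -0.42) and -2.13 for the cuticle (-1.36 and -1.34). For ABA- and dehydration-responsive genes 4 rose and 14 fell of 25 (5 and 14 adjusted over the list alone), with XERO2 (AT3G50970) at -3.86 ± 0.18. The median was -0.94 (adjusted p = 0.00142, and adjusted p = 0.374 with an estimated correlation). For aliphatic glucosinolates 2 rose and 11 fell of 16 (2 and 11 adjusted over the list alone), with MYB29 (AT5G07690) at -2.27 ± 0.24. The median was -0.66 (adjusted p = 0.00453, and adjusted p = 0.452 with an estimated correlation). Clock genes moved by phase. Of the morning-phased genes 6 of 7 rose (6 rose and 1 fell adjusted over the list alone), led by LHY (AT1G01060) (4.81 ± 0.16), and of the evening-phased genes 6 of 7 fell (6 adjusted over the list alone), led by FKF1 and PRR5 (AT5G24470) (-3.59 ± 0.17). Their medians were 1.57 and -2.00 (adjusted p = 0.000532 and 6.07e-05, and adjusted p = 0.186 and 0.0658 with an estimated correlation). The hour of harvest is not stated in the labels. Of the guard cell markers 7 of 9 fell (7 adjusted over the list alone), with ALMT12 (AT4G17970) at -1.22 ± 0.09, and of the dividing cell markers 6 of 6 fell (6 adjusted over the list alone). Their medians were -0.93 and -2.02 (adjusted p = 0.00124 and 0.000222, and adjusted p = 0.195 and 0.161 with an estimated correlation). The other 10 lists were not called. In the jasmonate/ethylene branch 10 rose and 2 fell of 16 (10 and 3 adjusted over the list alone, median 2.01, adjusted p = 0.0764), with ERF1 (AT3G23240) (3.63 ± 0.23) and PR4 (AT3G04720) (2.17 ± 0.28) up, and in salicylate synthesis and response 8 rose and 9 fell of 20 (8 and 9 adjusted over the list alone, median -0.23, adjusted p = 0.926), with FMO1 (AT1G19250) (5.07 ± 0.20) up and NIMIN1 (AT1G02450) (-2.35 ± 0.19) down, the test pointing up and the median down. The lists of ethylene, ABA synthesis, ion transport, flavonoids, hypoxia, the phloem, trichomes and reference genes had adjusted p = 0.116 to 0.926, the trichome test pointing down against a median of 0.13. Of the markers, CYP71A13 (5.40 ± 0.28), PR1 (4.69 ± 0.90), JAZ10 (2.14 ± 0.56) and SAG12 (4.43 ± 0.87, but 2.90 without infected replicate 2) rose, and RAB18 (-0.94 ± 0.24) and LHCB2.2 (-1.06 ± 0.22) fell. PDF1.2a rose (1.86 ± 0.66), but not without watered replicate 1 or infected replicate 1, 2 or 3 (adjusted p = 0.0547 to 0.147). RD29B fell (-1.79 ± 0.65), but not without watered replicate 1 or 3 or infected replicate 1, 2 or 3 (adjusted p = 0.0623 to 0.178), and RBCS1A fell (-0.28 ± 0.08), but not without watered replicate 1 (adjusted p = 0.0507). NCED3 (0.07 ± 0.23), LOX2 (0.20 ± 0.08) and VSP2 (-0.17 ± 0.28) were not called. CYP71A13 and its neighbour CYP71A12, the PDF1.2 copies, and the RBCS and LHCB genes are close relatives whose transcripts a probe may share.

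Infection after salt watering, set against salt-watered leaves on day 4, went with higher transcript of camalexin, salicylate and senescence genes and lower transcript of photosynthesis and aliphatic glucosinolate genes. KTI1 was 829.7-fold higher (9.70 ± 0.22, n = 3 per group), DOX1 683-fold (9.42 ± 0.17), and SAG12, a cysteine protease of senescing leaves, 451-fold (8.82 ± 0.87). PAD3 was 80.1-fold higher (6.32 ± 0.16) and PR1, a salicylate-induced secreted protein, 306-fold (8.26 ± 0.90). XTH31 (AT3G44990), a cell wall xyloglucan enzyme, was 272-fold lower (-8.09 ± 0.64), and the growth-promoting factors BEE2 (AT4G36540) and HBI1 (AT2G18300) 135-fold and 129.6-fold lower (-7.08 ± 0.35 and -7.02 ± 0.38). In total 17532 genes changed (8604 up, 8928 down), and 9026 passed 2-fold (3827 up, 5199 down). With each array centred on its median the split was 12320 up and 7739 down, or 61.4% up against 49.1%, since centring moved the median change of all genes from 0.07 to 0.24. Scaling to the reference genes moved it to -0.04. AOX1D (9.35 ± 0.16), CYP710A1 (9.04 ± 0.13), BGLU27 (8.76 ± 0.16), DXPS1 (8.57 ± 0.21), WRKY75 (8.54 ± 0.15) and GSTU3 (AT2G29470) (8.33 ± 0.14) were the other leading rises. The receptor-like kinase LYK3 (AT1G51940) (-7.10 ± 0.66), the expansin EXPA11 (AT1G20190) (-7.09 ± 0.38), MYB29 (-6.96 ± 0.24), the fatty acid elongation gene KCS8 (AT2G15090) (-6.94 ± 0.69), PnsB3 (AT3G16250) of the chloroplast NDH complex (-6.87 ± 0.58), RbcX1 (-6.83 ± 0.60) and RGF9 (AT5G64770) (-6.75 ± 0.20) were the other leading falls.

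Camera called 21 lists, 15 higher and 6 lower, and 0 with an estimated correlation (11 at unadjusted p under 0.05), and fry called 27. For pattern-triggered immunity 22 rose and 1 fell of 25 (22 and 1 adjusted over the list alone). The median was 1.17 (adjusted p = 3.21e-08, and adjusted p = 0.118 with an estimated correlation). In camalexin and tryptophan synthesis 18 of 18 rose (18 adjusted over the list alone), with ABCG40 at 7.43 ± 0.16. Camera gave adjusted p = 2.3e-11, and adjusted p = 0.0569 with an estimated correlation. In salicylate synthesis and response 14 rose and 1 fell of 20 (14 and 2 adjusted over the list alone), with FMO1 at 7.14 ± 0.20 and PBS3 (AT5G13320) at 4.56 ± 0.20. The median was 1.61 (adjusted p = 0.000268, and adjusted p = 0.259 with an estimated correlation). For leaf senescence 17 of 18 rose (17 adjusted over the list alone), with SAUR36 (AT2G45210) at 6.11 ± 0.20. The median was 3.40 (adjusted p = 4.52e-09, and adjusted p = 0.0774 with an estimated correlation). In ethylene synthesis and signalling 9 rose and 1 fell of 11 (9 and 1 adjusted over the list alone), with ACS2 (AT1G01480) at 7.49 ± 0.18, and in the hypoxia response 7 of 10 rose (7 adjusted over the list alone). Their medians were 1.81 and 0.93 (adjusted p = 0.00169 and 0.00478, and adjusted p = 0.0569 and 0.0827 with an estimated correlation). For the jasmonate MYC branch 11 of 14 rose (11 adjusted over the list alone), and for the jasmonate/ethylene branch 8 of 16 rose (8 adjusted over the list alone). Their medians were 1.53 and 0.90 (adjusted p = 0.000255 and 0.00535, and adjusted p = 0.259 and 0.259 with an estimated correlation). Of the heat shock proteins 11 of 11 rose (11 adjusted over the list alone), and of the oxidative stress genes 10 rose and 1 fell of 14 (10 and 1 adjusted over the list alone). Their medians were 4.62 and 1.22 (adjusted p = 9.43e-09 and 0.000301, and adjusted p = 0.0569 and 0.0569 with an estimated correlation). In the light reactions 36 of 36 fell (36 adjusted over the list alone), with LHCB4.2 (AT3G08940) at -2.46 ± 0.12 and LHCB2.2 at -4.08 ± 0.22. The median was -1.57 (adjusted p = 1.7e-16, and adjusted p = 0.135 with an estimated correlation). In the Calvin cycle 19 of 19 fell (19 adjusted over the list alone), with PRK (AT1G32060) at -1.81 ± 0.07 and the Rubisco subunit gene RBCS1B (AT5G38430) at -6.09 ± 0.27. The median was -1.24 (adjusted p = 6.7e-10, and adjusted p = 0.118 with an estimated correlation).

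In aliphatic glucosinolate synthesis 1 rose and 15 fell of 16 (1 and 15 adjusted over the list alone), with CYP83A1 (AT4G13770) at -3.71 ± 0.09 and BCAT4 at -4.18 ± 0.11. The median was -3.57 (adjusted p = 1.86e-09, and adjusted p = 0.118 with an estimated correlation). For cuticle synthesis 15 of 17 fell (15 adjusted over the list alone), with GPAT4 (AT1G01610) at -3.56 ± 0.20 and GPAT8 (AT4G00400) at -6.10 ± 0.41, enzymes of cutin synthesis. The median was -2.26 (adjusted p = 2.29e-06, and adjusted p = 0.0774 with an estimated correlation). Phenylpropanoids (14 rose and 1 fell of 15 (14 and 1 adjusted over the list alone)), indole glucosinolates (11 rose and 1 fell of 13 (11 and 1 adjusted over the list alone)) and jasmonate synthesis (11 rose and 3 fell of 16 (11 and 3 adjusted over the list alone)) were higher at adjusted p = 1.7e-05 to 0.0155, and at adjusted p = 0.0827 to 0.441 with an estimated correlation. Morning-phased clock genes were higher (5 of 7 rose (6 adjusted over the list alone)), and evening-phased ones (1 rose and 5 fell of 7 (1 and 6 adjusted over the list alone)) and dividing cell markers (5 of 6 fell (5 adjusted over the list alone)) lower, at adjusted p = 0.00229 to 0.0349, and at adjusted p = 0.185 to 0.259 with an estimated correlation. For ABA synthesis and signalling 19 rose and 6 fell of 32 (19 and 7 adjusted over the list alone), with ABA3 (AT1G16540) (2.15 ± 0.13) and CYP707A1 (AT4G19230) (3.16 ± 0.18) up and CYP707A2 down (-4.77 ± 0.27). The median was 0.50 (adjusted p = 0.0471, and adjusted p = 0.259 with an estimated correlation). This call was lost with median centring and without salt-watered replicate 3 or salt-watered infected replicate 2 (adjusted p = 0.0599 to 0.0725). The other 7 lists were not called (adjusted p = 0.0626 to 0.608). Of the markers NCED3 (2.21 ± 0.23), CYP71A13 (7.02 ± 0.28) and JAZ10 (4.06 ± 0.56) rose, and RAB18 (-1.17 ± 0.24) and RBCS1A (-0.89 ± 0.08) fell. RD29B -1.55 ± 0.65, PDF1.2a 0.34 ± 0.66, LOX2 0.15 ± 0.08 and VSP2 -0.56 ± 0.28 were not called.

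The responses to infection with and without salt shared many genes. Both rose 4771 genes, where independent lists of these sizes would share 1698.3, and both fell 6263 genes against 2237.3. Opposite calls numbered 320 and 460, against 1762.2 and 2156.1. The log2 changes, which have no array in common, correlated across genes at r = 0.805, and the slope of the response after salt on that without salt was 1.58 (jackknife SE over arrays 0.226).

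**Figure D3:**
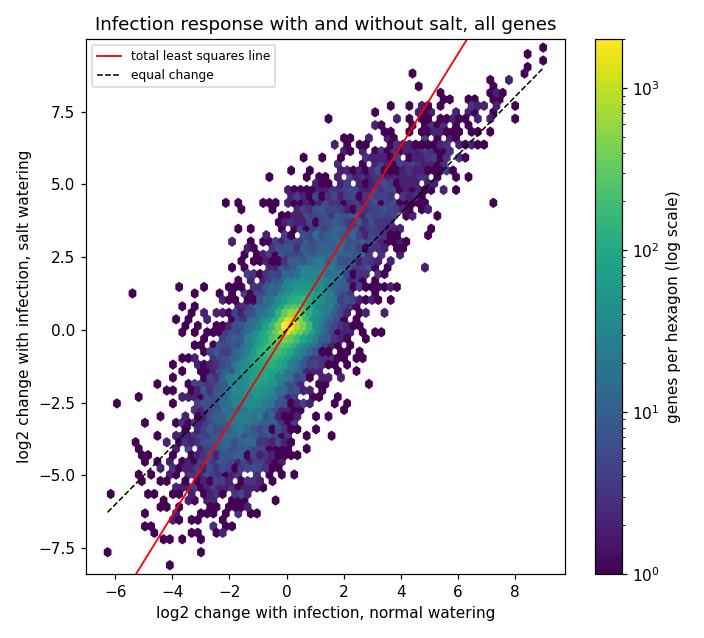
Log2 change with infection under salt watering (vertical) against that under normal watering (horizontal) for 32627 genes, as hexagons coloured by the number of genes on a log scale. The red line has the total least squares slope of 1.58 and the dashed line marks equal change. The log2 changes correlated at r = 0.805 across genes.

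Among infected leaves, those of salt-watered plants had less transcript of photosynthesis and aliphatic glucosinolate genes and more of senescence genes. LHCB2.2, an antenna protein gene of photosystem II, was 8.41-fold lower (-3.07 ± 0.22, n = 3 per group), RBCS1B 32.2-fold lower (-5.01 ± 0.27) and CYP83A1 of glucosinolate synthesis 7.21-fold lower (-2.85 ± 0.09). SAG12 was 22.0-fold higher (4.46 ± 0.87), the sugar transporter SWEET15 (AT5G13170) 38.0-fold (5.25 ± 1.00) and CEP1 (AT5G50260), a cysteine protease of dying cells, 28.6-fold (4.84 ± 0.22). SAG12 stood at 11.85 on infected replicate 2, against 7.17 and 7.39 on the other arrays of that group. PAD3 differed by 0.03 ± 0.16 (adjusted p = 0.924) and CYP71A13 by 0.03 ± 0.28 (adjusted p = 0.956). In all 11163 genes changed (5645 up, 5518 down), and 3776 passed 2-fold (1552 up, 2224 down). Scaling to the reference genes gave 4277 up and 6948 down, or 38.1% up against 50.6%, and moved the median change of all genes from 0.03 to -0.09. Without infected replicate 2, 12852 genes changed. Other leading rises were the transporter OCT1 (AT1G73220) (5.30 ± 0.36), the acid phosphatases PAP22 (AT3G52820) (5.23 ± 0.38) and PAP20 (AT3G52780) (4.44 ± 0.57), the response regulator RR16 (AT2G40670) (5.02 ± 0.19), the polygalacturonase ADPG1 (AT3G57510) (4.51 ± 0.17), the mannanase MAN1 (AT1G02310) (4.51 ± 0.26) and the cytokinin oxidase CKX2 (AT2G19500) (4.45 ± 0.29). Other leading falls were BEE2 (-5.02 ± 0.35), GASA6 (AT1G74670) (-4.83 ± 0.67), the receptor kinase BAM2 (AT3G49670) (-4.68 ± 0.19), ELP (AT1G12090) (-4.55 ± 0.24), the haemoglobin HB2 (AT3G10520) (-4.55 ± 0.40), DGR2 (AT5G25460) (-4.54 ± 0.33), the arabinogalactan protein FLA8 (AT2G45470) (-4.47 ± 0.23), HBI1 (-4.46 ± 0.38) and XTH7 (AT4G37800) (-4.42 ± 0.29).

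Camera called 12 lists, 8 higher and 4 lower, and 0 with an estimated correlation (7 at unadjusted p under 0.05), and fry called 20. In the light reactions 36 of 36 fell (36 adjusted over the list alone), including LHCB4.2 (-1.86 ± 0.12), and in the Calvin cycle 16 of 19 fell (17 adjusted over the list alone), including PRK (-1.42 ± 0.07). Their medians were -0.99 and -0.81 (adjusted p = 1.58e-22 and 1.2e-13, and adjusted p = 0.158 and 0.145 with an estimated correlation). In aliphatic glucosinolate synthesis 15 of 16 fell (15 adjusted over the list alone), with BCAT4 at -3.10 ± 0.11 and IPMI2 (AT2G43100) at -3.35 ± 0.14. The median was -2.35 (adjusted p = 9.47e-15, and adjusted p = 0.145 with an estimated correlation). For cuticle synthesis 3 rose and 10 fell of 17 (3 and 10 adjusted over the list alone). The median was -1.02 (adjusted p = 0.00448, and adjusted p = 0.275 with an estimated correlation). GPAT4 fell (-3.24 ± 0.20) and CER1 rose (3.99 ± 0.27). For leaf senescence 12 of 18 rose (12 adjusted over the list alone), with SAUR36 at 2.65 ± 0.20 and the chlorophyll breakdown genes NYC1 (AT4G13250) (0.92 ± 0.10) and SGR1 (AT4G22920) (1.00 ± 0.12). The median was 0.58 (adjusted p = 0.000212, and adjusted p = 0.245 with an estimated correlation). In salicylate synthesis and response 11 rose and 1 fell of 20 (12 and 1 adjusted over the list alone), with NIMIN1 (2.72 ± 0.19), PBS3 (1.52 ± 0.20) and FMO1 (1.33 ± 0.20) up and PR5 (AT1G75040) (-1.03 ± 0.13) down. The median was 0.82 (adjusted p = 0.00338, and adjusted p = 0.469 with an estimated correlation). For ABA- and dehydration-responsive genes 15 rose and 2 fell of 25 (16 and 2 adjusted over the list alone), with COR47 (AT1G20440) (1.73 ± 0.11) and ERD10 (AT1G20450) (1.23 ± 0.09) up. The median was 0.87 (adjusted p = 0.000353, and adjusted p = 0.387 with an estimated correlation). For ABA synthesis and signalling 18 rose and 4 fell of 32 (20 and 4 adjusted over the list alone), with AAO3 (AT2G27150) at 2.92 ± 0.32. The median was 0.44 (adjusted p = 0.00234, and adjusted p = 0.158 with an estimated correlation). For ethylene 6 of 11 rose (6 adjusted over the list alone), with ACS7 (AT4G26200) at 2.27 ± 0.20, and for heat shock proteins 6 of 11 rose (6 adjusted over the list alone). Their medians were 0.47 and 0.85 (adjusted p = 0.0128 and 0.00108, and adjusted p = 0.145 and 0.245 with an estimated correlation). For evening-phased clock genes 6 of 7 rose (6 adjusted over the list alone). The median was 0.93 (adjusted p = 0.000275, and adjusted p = 0.145 with an estimated correlation). For the hypoxia response 5 rose and 1 fell of 10 (5 and 1 adjusted over the list alone). The median was 0.46 (adjusted p = 0.0184, and adjusted p = 0.158 with an estimated correlation). The hypoxia call was lost without infected replicate 2 (adjusted p = 0.0613).

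The other 16 lists were not called. For camalexin and tryptophan synthesis 0 of 18 changed (0 adjusted over the list alone, median 0.03, adjusted p = 0.941), the test pointing down, and under the other scalings at most 1 member changed. At unadjusted p under 0.05, limma gave 0 of its members. In infected arrays 6 of the 18 members lay above 50% of the highest intensity on any array. For pattern-triggered immunity 4 rose and 1 fell of 25 (1 and 1 adjusted over the list alone, median 0.03, adjusted p = 0.726). In the jasmonate/ethylene branch 1 rose and 7 fell of 16 (1 and 7 adjusted over the list alone, median -0.30, adjusted p = 0.0832), with ORA59 (AT1G06160) (-2.11 ± 0.32) and ERF6 (-0.70 ± 0.14) down. The MYC branch, jasmonate synthesis, oxidative stress, ion transport, indole glucosinolates, phenylpropanoids, flavonoids and morning-phased clock genes had adjusted p = 0.0832 to 0.774, the flavonoid test pointing up against a median of -0.01. Of the reference genes 4 rose and 1 fell of 8 (4 and 1 adjusted over the list alone, median 0.21, adjusted p = 0.296). Markers of guard cells, the phloem, trichomes and dividing cells had adjusted p = 0.0726 to 0.448. Of the markers NCED3 rose (0.88 ± 0.23, but 0.58 without infected replicate 1), and PDF1.2a (-2.35 ± 0.66) and RBCS1A (-0.60 ± 0.08) fell. RD29B rose (2.24 ± 0.65), but not without salt-watered infected replicate 2 (adjusted p = 0.0514), and VSP2 rose (0.86 ± 0.28), but not without infected replicate 3 or salt-watered infected replicate 2 or 3 (adjusted p = 0.0639 to 0.12). RAB18 0.46 ± 0.24, PR1 1.34 ± 0.90, LOX2 0.02 ± 0.08 and JAZ10 0.08 ± 0.56 were not called. The effect of salt at day 4 and that in infected leaves, which share no array, correlated across genes at r = -0.0216. Of the genes that rose with salt at day 4, 545 rose and 567 fell with salt in infected leaves (345.0 and 337.2 for independent lists), and of those that fell 566 rose and 420 fell (407.1 and 397.9).

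The interaction asks whether infection changed a gene more, or less, after salt than without it. It equals the salt effect in infected leaves minus that at day 4. The infection response of SAG12 was higher after salt by 4.39 ± 1.23 on the log2 scale (n = 3 per group) and that of CEP1 by 4.71 ± 0.31. PAD3 had 2.50 ± 0.23 and NCED3 2.14 ± 0.33. LHCB2.2 had -3.02 ± 0.31, RBCS1B -4.73 ± 0.39 and GSTF12 -4.50 ± 0.61. In all 10381 genes passed, 5183 with a positive and 5198 with a negative interaction, and 5201 of them passed 2-fold (2427 and 2774). Median centring moved the median of all genes from 0.01 to 0.11, and scaling to the reference genes to -0.09. For PAD3 and GSTF12 the salt effect was -2.47 and 5.47 at day 4, and 0.03 and 0.97 (not called) among infected leaves. The largest positive values were those of SRO5 (AT5G62520) (6.15 ± 0.72), GA2OX2 (5.85 ± 0.39), PHI-1 (5.77 ± 0.68), PAP22 (5.38 ± 0.54), OCT1 (5.33 ± 0.51), the pectin methylesterase ATPMEPCRB (AT4G02330) (5.29 ± 0.48), TCH4 (4.85 ± 0.43), CML38 (4.70 ± 0.46) and MAN1 (4.67 ± 0.37). For PHI-1, TCH4 and CML38 the salt effect was -5.76, -4.49 and -4.00 at day 4, and 0.01, 0.36 and 0.70 (not called) among infected leaves. The largest negative values were those of TINY2 (AT5G11590) (-5.29 ± 0.25), BEE2 (-4.87 ± 0.49), BAM2 (-4.87 ± 0.27), RGF9 (-4.80 ± 0.29), MYB29 (-4.69 ± 0.35), GASA6 (-4.54 ± 0.94), HB2 (-4.50 ± 0.57) and HBI1 (-4.50 ± 0.54).

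Camera called 18 lists, 13 positive and 5 negative, and fry 22. With an estimated correlation camera called 1 (9 at unadjusted p under 0.05), ethylene synthesis and signalling: 9 of 11 rose (9 adjusted over the list alone), with ACS7 at 2.26 ± 0.28. The median was 0.79 (adjusted p = 0.000104, and adjusted p = 0.048 with an estimated correlation). Rises and falls in these list counts are positive and negative interactions. In salicylate synthesis and response 17 of 20 rose (18 adjusted over the list alone), with NIMIN1 at 3.56 ± 0.27 and SARD1 at 3.27 ± 0.36. The median was 1.88 (adjusted p = 3.06e-08, and adjusted p = 0.149 with an estimated correlation). For leaf senescence 15 of 18 rose (17 adjusted over the list alone), and for pattern-triggered immunity 13 of 25 rose (17 adjusted over the list alone). Their medians were 1.34 and 0.64 (adjusted p = 1.36e-08 and 3.48e-06, and adjusted p = 0.0851 and 0.179 with an estimated correlation). For camalexin 9 of 18 rose (9 adjusted over the list alone), and for the MYC branch 6 of 14 rose (6 adjusted over the list alone). Their medians were 0.59 and 0.82 (adjusted p = 0.000166 and 0.00157, and adjusted p = 0.176 and 0.374 with an estimated correlation). Among infected leaves the salt effect had medians of 0.03 for camalexin, 0.03 for pattern-triggered immunity, 0.05 for the MYC branch and -0.01 for flavonoids (not called), against -0.52, -0.63, -0.92 and 1.01 at day 4. For ABA synthesis and signalling 14 rose and 1 fell of 32 (16 and 1 adjusted over the list alone), and for dehydration-responsive genes 11 rose and 2 fell of 25 (11 and 2 adjusted over the list alone), the latter lost without watered replicate 3 (adjusted p = 0.0855). Their medians were 0.48 and 0.58 (adjusted p = 0.000255 and 0.0156, and adjusted p = 0.0851 and 0.461 with an estimated correlation). In the light reactions 34 of 36 fell (35 adjusted over the list alone), and in the Calvin cycle 16 of 19 fell (16 adjusted over the list alone). Their medians were -0.94 and -0.84 (adjusted p = 5.89e-17 and 9.49e-12, and adjusted p = 0.168 and 0.103 with an estimated correlation). In aliphatic glucosinolates 15 of 16 fell (15 adjusted over the list alone), and in flavonoids 7 of 15 fell (8 adjusted over the list alone). Their medians were -3.12 and -1.02 (adjusted p = 3.17e-16 and 0.00236, and adjusted p = 0.0851 and 0.333 with an estimated correlation). The cuticle list (3 rose and 9 fell of 17 (3 and 10 adjusted over the list alone)) was negative, and hypoxia (7 of 10 rose (7 rose and 1 fell adjusted over the list alone)), oxidative stress (6 rose and 2 fell of 14 (7 and 2 adjusted over the list alone)), heat shock proteins (5 rose and 2 fell of 11 (6 and 2 adjusted over the list alone)) and evening-phased clock genes (6 of 7 rose (6 adjusted over the list alone)) were positive, at adjusted p = 0.000908 to 0.0222, and at adjusted p = 0.0851 to 0.374 with an estimated correlation. Of the guard cell markers 3 of 9 rose (3 adjusted over the list alone). The median was 0.23 (adjusted p = 0.0458, and adjusted p = 0.374 with an estimated correlation). This call was lost with median centring and without watered replicate 1, salt-watered replicate 3, infected replicate 2 or 3, or salt-watered infected replicate 1 or 3 (adjusted p = 0.0523 to 0.138). The other 10 lists were not called (adjusted p = 0.0778 to 0.542). Of the other markers CYP71A13 (1.62 ± 0.40) and RBCS1A (-0.61 ± 0.12) passed. PR1 passed (3.56 ± 1.28, adjusted p = 0.0495), but not with any single array of these 4 groups left out other than watered replicate 3 or infected replicate 3 (adjusted p = 0.0731 to 0.116). RD29B 0.25 ± 0.92, RAB18 -0.24 ± 0.34, PDF1.2a -1.52 ± 0.94, LOX2 -0.05 ± 0.11, VSP2 -0.39 ± 0.39 and JAZ10 1.91 ± 0.79 did not.

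Salt and infection together, set against watered leaves, changed 17568 genes (8871 up, 8697 down), of which 8826 passed 2-fold (3732 up, 5094 down). KTI1 was 958-fold higher (9.90 ± 0.22, n = 3 per group), followed by DOX1 (9.53 ± 0.17), AOX1D (9.42 ± 0.16), CSLG2 (9.35 ± 0.27) and CYP710A1 (9.02 ± 0.13). KCS8 was 189-fold lower (-7.56 ± 0.69), followed by BEE2 (-7.22 ± 0.35), LYK3 (-7.16 ± 0.66), GASA6 (-7.00 ± 0.67) and HBI1 (-6.97 ± 0.38). With median centring 12543 rose and 7604 fell, or 62.3% up against 50.5%, and the median change of all genes moved from 0.12 to 0.28. It was -0.01 with reference gene scaling. Camera called 17 lists, 11 higher and 6 lower, and 0 with an estimated correlation (7 at unadjusted p under 0.05), and fry called 26. In the light reactions 36 of 36 fell (36 adjusted over the list alone), and in aliphatic glucosinolates 1 rose and 15 fell of 16 (1 and 15 adjusted over the list alone). Their medians were -1.58 and -3.25 (adjusted p = 1.53e-17 and 8.67e-09, and adjusted p = 0.157 and 0.157 with an estimated correlation). In camalexin synthesis 17 of 18 rose (18 adjusted over the list alone), and in leaf senescence 15 rose and 1 fell of 18 (15 and 1 adjusted over the list alone). Their medians were 1.92 and 2.16 (adjusted p = 4.54e-09 and 1.47e-06, and adjusted p = 0.121 and 0.157 with an estimated correlation). Heat shock proteins (11 of 11 rose (11 adjusted over the list alone)), phenylpropanoids (14 rose and 1 fell of 15 (14 and 1 adjusted over the list alone)), pattern-triggered immunity (17 rose and 3 fell of 25 (17 and 3 adjusted over the list alone)), the MYC branch (11 of 14 rose (11 adjusted over the list alone)), oxidative stress (11 rose and 2 fell of 14 (11 and 2 adjusted over the list alone)), ethylene (7 rose and 2 fell of 11 (7 and 2 adjusted over the list alone)), indole glucosinolates (7 rose and 2 fell of 13 (10 and 2 adjusted over the list alone)) and morning-phased clock genes (5 of 7 rose (5 adjusted over the list alone)) were higher, at adjusted p = 8.67e-09 to 0.0294, and at adjusted p = 0.121 to 0.538 with an estimated correlation. The Calvin cycle (19 of 19 fell (19 adjusted over the list alone)), the cuticle (15 of 17 fell (15 adjusted over the list alone)), dividing cells (6 of 6 fell (6 adjusted over the list alone)) and evening-phased clock genes (1 rose and 5 fell of 7 (1 and 5 adjusted over the list alone)) were lower, at adjusted p = 4.83e-10 to 0.0294, and at adjusted p = 0.121 to 0.16 with an estimated correlation. For hypoxia 6 rose and 1 fell of 10 (6 and 2 adjusted over the list alone), a call lost with median centring and without watered replicate 2 (adjusted p = 0.0784 and 0.0556). The median was 1.02 (adjusted p = 0.0419, and adjusted p = 0.16 with an estimated correlation). The other 11 lists were not called (adjusted p = 0.107 to 0.677). Among them the test and the median differed in sign for dehydration-responsive genes (median 0.12) and the jasmonate/ethylene branch (median -0.15). Of the markers SAG12 (8.88 ± 0.87), PR1 (6.04 ± 0.90), CYP71A13 (5.43 ± 0.28), NCED3 (0.95 ± 0.23) and JAZ10 (2.22 ± 0.56) rose, and LHCB2.2 (-4.13 ± 0.22) and RBCS1A (-0.88 ± 0.08) fell. LOX2 rose (0.23 ± 0.08), but not without watered replicate 2 or 3 or salt-watered infected replicate 1 or 2 (adjusted p = 0.0527 to 0.088), and VSP2 rose (0.70 ± 0.28), but not without watered replicate 1 or 3 or salt-watered infected replicate 2 or 3 (adjusted p = 0.0618 to 0.185). RD29B 0.45 ± 0.65, RAB18 -0.48 ± 0.24 and PDF1.2a -0.50 ± 0.66 were not called.

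The log2 changes of the salt and the infection responses correlated across genes at r = 0.0966. Both comparisons use the watered arrays, and unchanged groups simulated against those arrays gave r = 0.498. The observed covariance was 0.0466 and the simulated one 0.0221, a difference of 0.0246. Shared calls were 826 genes that rose in both and 967 that fell in both, where independent lists would share 393.6 and 589.6. Opposite calls were 480 genes that rose with salt and fell with infection (499.7 for independent lists) and 809 that fell with salt and rose with infection (464.4). The 3 watered arrays were not split between the comparisons, so part of the excess may come from the shared arrays.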

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

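The tests on the shift of the controls, the mechanical stimulus, the common proportion and the carried-over salt effect were chosen after the result was seen. The tests on single arrays and on other splits were not.

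The difference between the infection responses with and without salt passed for 10381 genes. By camera it passed for 18 gene lists, of which only ethylene passed with an estimated correlation (adjusted p = 0.048, others 0.0851 to 0.461). The medians were 1.88 for salicylate, 1.58 for evening-phased clock genes, 1.34 for senescence, 0.89 for hypoxia, 0.82 for the jasmonate MYC branch, 0.82 for heat shock proteins and 0.79 for ethylene. They were 0.64 for pattern-triggered immunity, 0.59 for camalexin, 0.59 for oxidative stress, 0.58 for dehydration-responsive genes, 0.48 for ABA metabolism and signalling and 0.23 for guard cells, and on the other side -3.12 for aliphatic glucosinolates, -1.02 for flavonoids, -0.94 for the light reactions, -0.94 for the cuticle and -0.84 for the Calvin cycle. For camalexin, pattern-triggered immunity, the MYC branch and flavonoids the salt effect had medians of -0.52, -0.63, -0.92 and 1.01 at day 4, and 0.03, 0.03, 0.05 and -0.01 among infected leaves (not called). For salicylate they were -0.86 and 0.82. The fixed markers that passed were SAG12 (4.39), PR1 (3.56), PAD3 (2.50), NCED3 (2.14), CYP71A13 (1.62), RBCS1A (-0.61) and LHCB2.2 (-3.02), of which PR1 failed with single arrays left out (adjusted p = 0.0731 to 0.116). Guard cells and dehydration-responsive genes also lost their calls this way.

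Over all genes infection changed expression more after salt (slope 1.58). Some lists had smaller medians after salt, such as evening-phased clock genes (-0.77 against -2.00) and the jasmonate/ethylene branch (0.90 against 2.01). The light reaction median of salt-watered infected against infected leaves was -0.990. It was -1.12 without infected replicate 2, which lay apart, and -0.882 at its smallest, without replicate 1. This argues against a single infected array as source. More diseased tissue scaling every gene by 1 common proportion would give every list the same linear ratio. The linear ratio of both responses, each against watered leaves, was 1.02 for camalexin (0.964 to 1.07 with 1 array left out). It was 2.05 for photosynthesis (1.89 to 2.45) and 1.05 over the 12 camalexin members not above 50% of the highest intensity. Among infected leaves, r = -0.0216 between both salt effects argues against a lasting day 4 effect as sole cause. It would cancel in the slope, which r cannot test. A faster course of disease or a changed defence after salt, for which camalexin genes may already have been at a plateau, stays open and untested, as does any salt watering after day 4. So does the shift of the watered leaves since day 0, which enters slope and interaction but not comparisons of infected leaves.

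The 4 defence lists of salicylate, pattern-triggered immunity, camalexin and the jasmonate/ethylene branch (79 members) had a median of -0.77 in salt-watered against watered leaves, and of 0.42 in watered against day 0 leaves. A rise in the watered leaves as the whole cause is argued against for the first 3 lists, with a median against day 0 of -0.279 (-0.324 to -0.193 with 1 array left out), though 8 of their 63 members fell and camera gave adjusted p = 0.129 to 0.207 with an estimated correlation, and stays open for the jasmonate/ethylene branch, at -0.116 (-0.203 to 0.0689, camera adjusted p = 0.252). A single watered array is argued against by a median of -0.690 or lower (-0.785 to -0.690). A mechanical stimulus of the watered leaves before harvest may account for part of it: 10 touch- and wound-responsive genes, none in another list, had a median of 1.16 in watered against day 0 leaves (7 rose, 0 fell, camera p = 3.39e-12 and p = 0.00301 with an estimated correlation). Such genes also respond to other stimuli, the hour of harvest is not stated, and an effect of salt itself stays open.

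For each comparison of 3 arrays with 3, only the real one of 10 splits gave as many genes, too few splits for a share under 0.05. Real and highest other counts were 4347 and 0 for salt, 14616 and 0 for infection, 17532 and 0 for infection after salt, 11163 and 1 for salt in infected leaves, 1394 and 1 for time, and 17568 and 0 for both treatments. For the interaction, fitted on its 12 arrays, the real arrangement gave 9492 genes and the highest of the others 4388. As 1 of 100 gave as many, chance may give part but hardly all of the count.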

How the results depend on the processing

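The settings with day 0 leaves as the control, reference gene scaling, the residual component and gene-by-gene array weights were chosen after the data were seen. Of 10029 values of named genes under alternative settings, 9760 kept their direction and side of the threshold, 198 were no longer past it, 64 newly passed and 7 reversed. With 1 array left out, 5670 of 5964 were kept, 288 were no longer past it, 6 newly passed and 0 reversed. All reversed values have day 0 leaves as control (562 genes for salt). For salt they were RRTF1 0.17, HAI1 1.00, ACS6 0.00075, NCED3 0.43 and SLAC1 -0.10, and for both treatments ERF104 0.069 and ALMT12 0.19. Camera reversed 0 of its list calls.

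A 2-fold minimum left 1251 genes for salt, 6132 for infection, 9026 for infection after salt, 3776 for salt in infected leaves, 5201 for the interaction, 515 for time and 8826 for both treatments, and treat against 1.5-fold 670, 5762, 9442, 3162, 3327, 183 and 9059, by construction. Array weights (0.130 to 43.4), whose default estimate stopped before it converged, gave 20672 for salt, 27234 for infection, 21470 for salt in infected leaves, 23376 for the interaction and 12963 for time, and gene-by-gene weights 10844, 16494 and 6469 for salt, the interaction and time. The time count was 885 with only the groups compared and 2185 with the residual component. The cause was not tested. Camera with an estimated correlation called 0 lists in 6 comparisons and 1 in the interaction, and fry 20 for salt in infected leaves and 26 for both treatments. By Spearman the agreements were -0.113 between the salt effects, 0.681 between the infection responses and 0.229 between salt and infection.

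With 1 array left out, the counts ranged over 2728 to 3904 for salt, 13380 to 14835 for infection, 16019 to 17191 for infection after salt, 9386 to 12852 for salt in infected leaves, 9023 to 11986 for the interaction, 746 to 1236 for time and 16199 to 17519 for both treatments, and the lists called over 11 to 13, 17 to 19, 20 to 21, 12 to 13, 17 to 19, 10 to 12 and 16 to 17 in that order. The agreements ranged over -0.0317 to -0.0119, 0.764 to 0.816 (slope 1.46 to 1.77) and 0.0413 to 0.183. Without infected replicate 2, infection gave 13461 genes. The replicate numbers did not pair the arrays: 30 same-number pairs had a median r of -0.0444 (8 over 0.1), and 1 of 15 arrays correlated best with its own number. The replicate block gave 3972, 14247, 17230, 10816, 9965, 1260 and 17155 genes in that order. Low intensity and the top of the range limit what the arrays can show, beside their number.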

Other observations

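The gene families described here were chosen after the data were seen, so their tests are exploratory (26 families, 182 tests with camera). In salt-watered against watered leaves, 11 of 19 ERF transcription factors fell (median -0.91, adjusted p = 6.56e-10), as did 6 of 8 calmodulin-like proteins (-1.41, adjusted p = 1.1e-07). Of 30 xyloglucan endotransglucosylases, which remodel cell walls, 1 rose and 12 fell (-0.40, adjusted p = 1.13e-05), and of 30 arabinogalactan proteins 1 rose and 12 fell (-0.36, adjusted p = 3.37e-08). Each had adjusted p = 0.0343 with an estimated correlation. From day 0 to day 4, a comparison that shares the watered arrays and for which unchanged groups gave r = -0.501 with the salt changes, these families had 9 ERF factors up and 1 down (0.55), and 4 calmodulin-like (0.75), 4 xyloglucan (0.18) and 2 arabinogalactan members (0.24) up (adjusted p = 4.35e-12 to 0.000838, and adjusted p = 0.0562 to 0.112 with an estimated correlation).

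In infected against watered leaves, 43 of 58 UDP-glycosyltransferases rose and 9 fell (median 1.04, adjusted p = 3.24e-08, and adjusted p = 0.039 with an estimated correlation), and 19 of 27 tau class glutathione transferases rose and 5 fell (1.26, adjusted p = 3.98e-06, and adjusted p = 0.0685 with an estimated correlation). Of 107 mitochondrion-encoded genes 93 rose (1.23, adjusted p = 8.96e-19, and adjusted p = 0.377 with an estimated correlation). In salt-watered infected against infected leaves, 17 of 19 autophagy genes rose and 1 fell (0.90, adjusted p = 1.32e-08, and adjusted p = 0.183 with an estimated correlation), while 13 of 16 SAUR auxin-responsive genes fell and 1 rose (-1.82, adjusted p = 2.49e-06, and adjusted p = 0.323 with an estimated correlation) and 25 of 87 plastid-encoded genes fell (-0.40, adjusted p = 1.64e-07, and adjusted p = 0.594 with an estimated correlation). These directions held under the 3 other scalings of the arrays.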
